A study of Mus musculus with 12 samples.

How the data were processed

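Expression was measured in lung RNA from 12 mice on Agilent mouse arrays (design 14868, 1 colour), 3 arrays in each of the groups PBS, LPS, NNK and LPS/NNK, as the labels assign them. The deposited scanner files give an intensity for each of 45018 spots, of which 43379 are not controls. Per the file headers they were made by Agilent Feature Extraction 10.7.3.1 (the labels give 10.7), which subtracted the background and detrended the processed signal within each array and did not scale arrays to each other. The deposited table of the series gives log2 values that, per the labels' protocols, were made with Partek (no version given). They equalled the values computed here, log2 of the processed signal minus the 75th percentile of each array, with a largest spread of 4.54e-05. The marks that a spot is well above background, an outlier or saturated are those of the scanner software, per the file headers. No spot was saturated.

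Outlier spots (39 to 99 per array) were left out and the remaining spots of a probe averaged, which gave 41174 probes; 37 probes with only outlier spots on some array were dropped. Gene names came from RefSeq accessions alone, since the files hold no column of gene names: 24375 probes (59.2%) had a symbol, for 17016 genes. The others kept their identifier. Genomic positions were not used here. A probe was kept where it was well above background on every array of at least 1 group (27889 probes for PBS, 21336 for LPS, 24498 for NNK and 22170 for LPS/NNK), which left 28331 probes. The probe with the highest mean over the 12 arrays stood for its gene, giving 21853 items. For 3400 genes with several probes, the changes of the probes correlated at r = 0.825 (LPS against PBS), 0.805 (NNK against PBS), 0.586 (LPS/NNK against PBS), 0.542 (LPS/NNK against NNK), 0.361 (LPS/NNK against LPS) and 0.789 (interaction).

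All 12 arrays entered 1 fit with a mean per group in limma 3.58.1 (lmFit and eBayes, R 4.3.3 and the data.table package at 1.17.8), with 8 residual and 5.5 prior degrees of freedom, for 5 comparisons of groups and the interaction of LPS and NNK. An item was called at a Benjamini-Hochberg adjusted p under 0.05 from limma's moderated test, 2-sided. The smallest p that an exact permutation test of 3 arrays against 3 can give is 0.1, so no exact test could pass. Figures were drawn with Python 3.11.15. Gene lists were compared with other genes by camera with a preset correlation of 0.01, adjusted over 162 tests (27 lists in 6 comparisons), and again with an estimated correlation; fry tested whether a list moves on balance 1 way. Counts of list members are given over all items tested and adjusted over the list alone.

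The lists, tests, comparisons, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap (no such condition for the interaction), passing over clone names and bare identifiers, then up to 4 members of each list with the smallest p, and every member of a count of 5 or fewer. The text gives the 16 genes of the first part, except for 1 item that is not reported here, and, of the others, mostly those with the smallest p in their list. The genes of the sex chromosomes were chosen after the data were seen, and the genes of the interaction other than the largest come from the lists.

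The test was tried on simulated data with known answers, 500 changed genes per fold over 10 draws. In the group comparisons it recovered 0.6% to 1.4% of genes changed 1.5-fold, 15% to 17.4% at 2-fold, 74.2% to 79% at 4-fold and 91.8% to 95.4% at 8-fold, and in the interaction 0.2%, 1.2%, 42.2% and 71%, with no wrong sign. Of all calls 4.18% to 6.06% were false. Few genes were changed in each draw, and the noise was independent between genes. In the real comparisons with PBS 51.5% to 56% of items were called, so these shares do not describe them. A shifted list was called in 10 of 10 draws and a list with no shift in 0 of 10. With the residuals of the real arrays regrouped 100 times for LPS/NNK against NNK, camera with the preset correlation called a median of 8 of 27 lists (highest 16) and any list in 98 regroupings, against 2 regroupings with an estimated correlation (highest 1 list); limma called a median of 0 items (highest 2854). The preset therefore calls lists whose genes vary together between mice.

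Slides and scans were read from the file headers. Slide 5 held PBS 3 and NNK 2, slide 6 NNK 3 and LPS/NNK 2, slide 7 NNK 5 and LPS/NNK 3, slide 8 PBS 1 and LPS/NNK 6; PBS 2 lay on slide 1 and LPS 1, 5 and 6 on slides 2, 3 and 4. Slides 1 to 4 and 5 to 8 form 2 series of slide numbers. The position on the slide followed the group. Arrays on the same slide had a consensus correlation of 0.241. A fit with the slide as a fixed effect is given for the comparisons whose groups share a slide. It uses only the arrays of slides 5 to 8, without PBS 2 and the LPS arrays, and leaves few residual degrees of freedom. Alternatives were normexp background correction (offset 50) on the median spot and background signals, because the mean spot signal that was planned is not among the columns of the files. Others were quantile normalization, the median of the tested genes, no filter, a filter on all 12 arrays (20393 probes), every probe or the mean of probes, other moderation, fewer samples, blocks, and an absolute log2 fold change of at least 1. Cyclic loess, the slide series as a term and PBS 3 as the only PBS array were added after the data were seen, the last because PBS 1 and PBS 2 show Y-linked transcripts although the labels say female. With 1 array, that array is assumed to vary like the arrays of the other groups. PBS 2 is the only PBS array in the slide series of the LPS arrays, and it alone of the 12 arrays was scanned on a different day. With the slide series as a term, LPS against PBS, also within the interaction, is therefore LPS against PBS 2 alone. NNK and LPS/NNK are then set against PBS 1 and PBS 3.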

Results

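RNA of lung tissue from FVB/N mice was measured on 12 Agilent arrays in 1 colour, each array from 1 mouse. The labels give female mice, aged 7 weeks at the start. Mice fell into 4 groups: PBS as the vehicle, LPS (bacterial endotoxin, 5 ug per mouse into the nose each week for 16 weeks), NNK (a nitrosamine carcinogen of tobacco, 3 mg per mouse into the peritoneum during the first 4 weeks) and LPS with NNK, written LPS/NNK. Each group had 3 arrays: PBS 1, 2 and 3, LPS 1, 5 and 6, NNK 2, 3 and 5, and LPS/NNK 2, 3 and 6. By the labels the PBS mice received PBS for 16 weeks, and no vehicle is named for the NNK mice. NNK against PBS and LPS/NNK against NNK may therefore also differ in the dosing itself. Mice were killed 1 week after the last treatment. The sources used here do not say whether mice given NNK alone had the same age at death as the others, or whether tumour tissue was part of the sample.

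Signal and array quality differed between groups. On the PBS arrays 70.2% to 73.1% of spots were well above background, against 55.6% to 67.5% on the treated arrays. The 75th percentile of brightness was 699 to 984 in PBS and 183 to 510 in the treated groups, whereas the control RNA added during labelling (spike-in) was dimmer in PBS (median log2 signal 9.12 to 10.13) than in the treated groups (10.47 to 11.65). The number of arrays, 3 per group, limits the precision of each comparison. Of 41174 probes, 28331 were well above background on every array of at least 1 group, and they gave 21853 items for testing: 13645 named genes and 8208 probes known by an identifier alone.

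**Figure D1:**
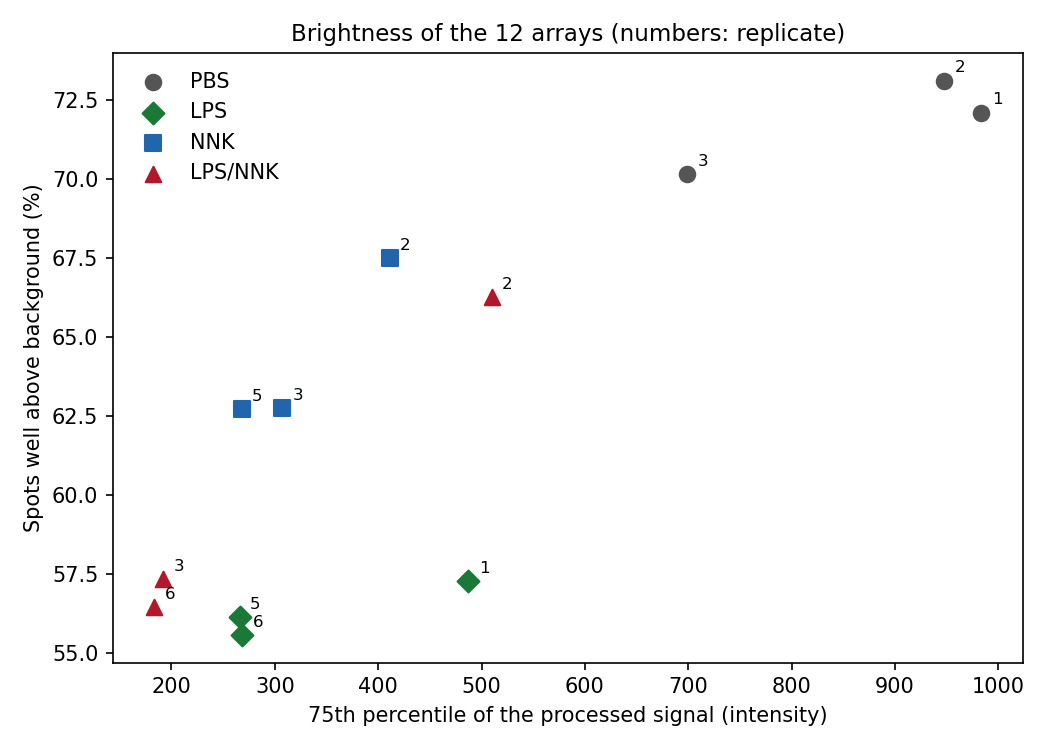
Brightness of each array. Each point is 1 array, coloured by treatment and numbered by replicate, with the 75th percentile of processed signal (intensity) on the horizontal axis and the share of spots well above background (percent) on the vertical axis. PBS arrays reached 699 to 984 intensity units, and no treated array exceeded 510.

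The PBS arrays stood apart from all 9 treated arrays. The first principal component of the normalized values held 52.4% of the variance and placed PBS at -119 to -143 and the treated arrays at 0.187 to 74.3; the second held 15.4%. The correlation across genes between a PBS array and a treated array was 0.878 to 0.933, against 0.978 to 0.984 within PBS and 0.942 to 0.990 among the treated arrays. Genes of the sex chromosomes split the PBS group. Xist, the transcript of the inactive X chromosome, was not above background in PBS 1 and PBS 2 (log2 -8.43 and -8.40), and the Y-linked genes Ddx3y (0.83 and 1), Eif2s3y (1.37 and 1.51), Kdm5d (-1.78 and -1.52) and Uty (-3.16 and -2.41) were well above it. In PBS 3 and all 9 treated arrays Xist was well above background and none of these 4 Y-linked genes was. The labels call all mice female.

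**Figure D2:**
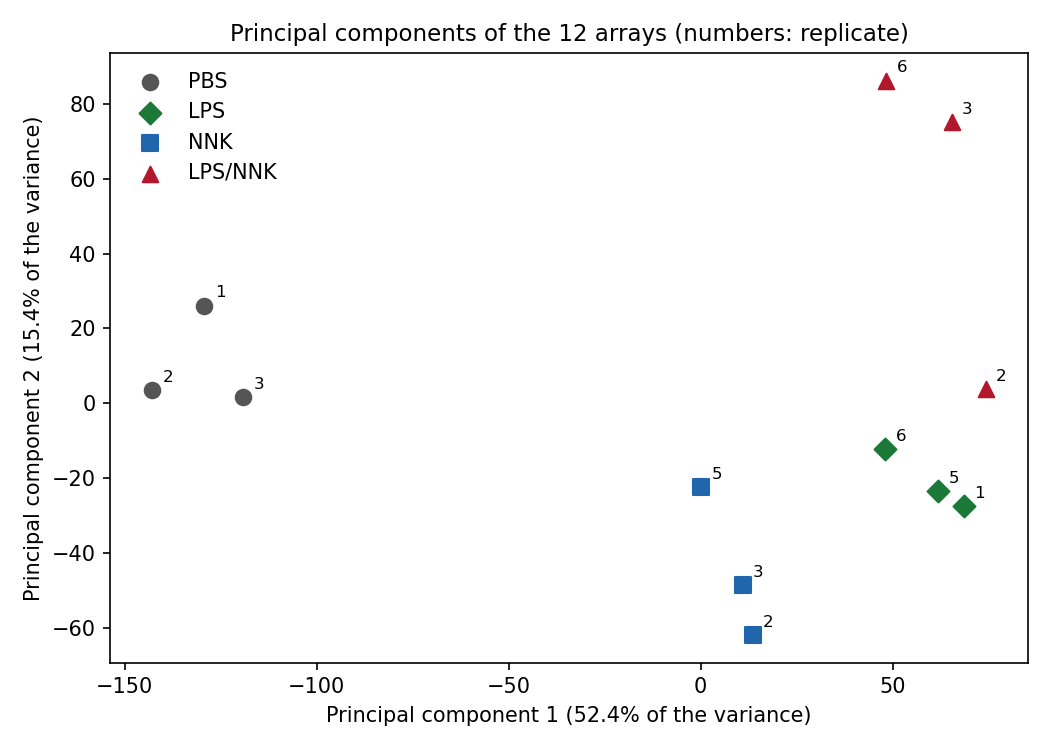
Principal components of the 12 arrays. Each point is 1 array, coloured by treatment; the axes are scores (log2 units) on the first component (52.4% of the variance) and the second (15.4%). PBS arrays lie at -119 to -143 on the first component and treated arrays at 0.187 to 74.3.

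LPS/NNK against NNK asks what weekly endotoxin added in lungs of mice that had also received the carcinogen. The labels name no vehicle for the NNK mice, so the weekly dosing itself may differ too. In this and the following comparisons changes are log2 fold changes with their standard error (SE) from limma, n = 3 arrays per group, and the arrays of the groups did not overlap for any gene said to rise or fall unless this is stated. Ifng, the cytokine of activated T and natural killer cells, rose by 5.22 (SE 0.43, adjusted p = 3.78e-05). Cxcl9 (6.99, SE 0.97, adjusted p = 0.000633) and Cxcl10 (5.34, SE 1.02, adjusted p = 0.00443), chemokines that draw T cells, rose with Cxcr6, a chemokine receptor of T cells (4.54, SE 0.33, adjusted p = 2.84e-05). Ubd, a ubiquitin-like modifier, was at least 111-fold higher (adjusted p = 0.000247), and Gbp2b, a guanylate-binding protein, at least 22.7-fold higher (adjusted p = 0.000584). A fold is given as "at least" where no array of the dimmer group was above background; it was computed against the dimmest signal that still counted as above background on those arrays. C1qtnf3, at least 10.6-fold higher (adjusted p = 3.61e-07, but a log2 change of 0.746 and adjusted p = 0.693 after normexp background correction), and Apol7c (4.85, SE 0.52, adjusted p = 0.00014) complete the 8 largest rises. Normexp ended the calls of Gbp2b (1.37), C1qtnf3 and Apol7c (0.92), and Apol7c was well above background on 1 of 3 NNK arrays.

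The 8 largest falls had adjusted p from 0.000342 to 0.041. Cd209b, a lectin of macrophages, fell by 4.06 (SE 0.77), Ccl24, a chemokine for eosinophils, by 3.24 (SE 0.40), and Bpifa1, a secreted protein of the upper airway, by 3.38 (SE 1.05). Hamp, which encodes the iron hormone hepcidin, fell by 3.12 (SE 0.57), Npy (neuropeptide Y) by 3.40 (SE 0.53), Adrb1, the beta-1 adrenergic receptor, by 3.24 (SE 0.49), Cst8 by 3.54 (SE 0.59) and Cdk5r2 by 3.06 (SE 0.92). The calls of Bpifa1 and Cdk5r2 held in 10 and 11 of 20 alternative settings. Normexp ended all 8 calls but that of Adrb1, with Cd209b at -1.14, Ccl24 at -0.767, Bpifa1 at -2.81, Hamp at -0.948, Npy at -1.22, Cst8 at -1.31 and Cdk5r2 at -2.44. On the LPS/NNK arrays Cd209b, Ccl24 and Npy were well above background on 1 of 3 and Hamp and Cst8 on 2 of 3. Across all items 3773 changed at an adjusted p under 0.05, 1731 higher and 2042 lower, of which 2923 by a log2 of at least 1; 2349 were named genes, 1213 higher and 1136 lower. The count moved when single arrays were left out, which also leaves fewer arrays to detect a change. It was 1631 without NNK 2, 1576 without NNK 3, 2950 without NNK 5, 1790 without LPS/NNK 3 and 2025 without LPS/NNK 6. Only without LPS/NNK 2 did it rise, to 5813. With no filter on dim probes it was 2515. Arrays of the groups did not overlap for 35.9% of items, where chance gives 10%.

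**Figure D3:**
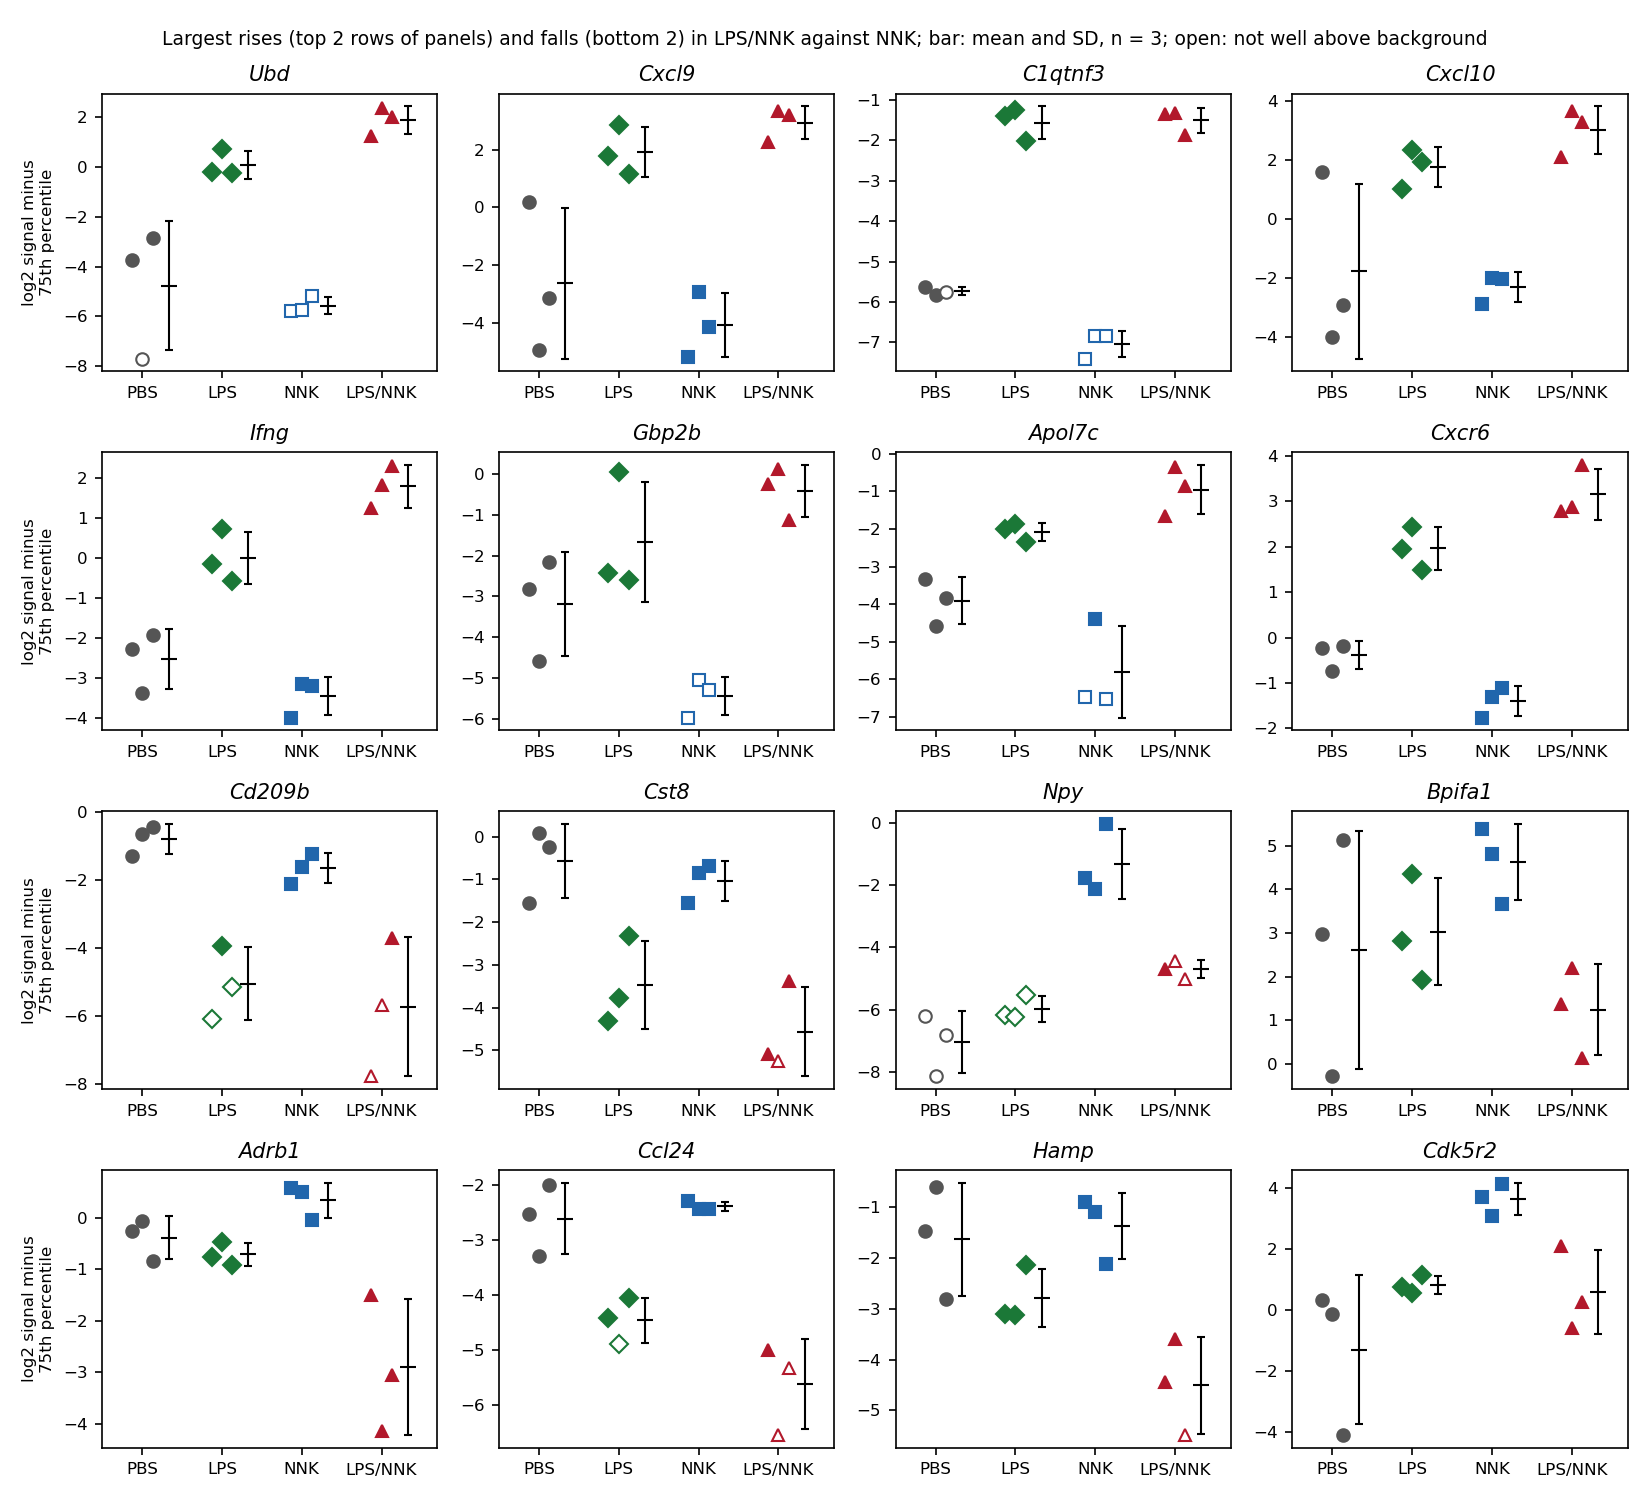
The 8 largest rises and 8 largest falls of LPS/NNK against NNK. Each panel is 1 gene, with the log2 signal minus the 75th percentile of the array on the vertical axis, 1 point per array in each of the 4 groups on the horizontal axis, and a bar at the mean with the standard deviation (n = 3); open points are not well above background. Ubd averaged 1.9 in LPS/NNK and -5.6 in NNK.

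Of 35 measured interferon response genes 20 rose and none fell (26 rose adjusted over the list alone), and the median change was 1.44 (camera adjusted p = 1.75e-13; adjusted p = 0.519 with an estimated correlation). Ifi205 rose by 2.42 (SE 0.31), Iigp1, an immunity-related GTPase, by 4.00 (SE 0.56), and Irgm1 by 2.68 (SE 0.41). Of 34 proliferation genes 17 rose and none fell (23 adjusted over the list alone), median 1.06 (camera adjusted p = 2.1e-09; adjusted p = 0.572 with an estimated correlation). The rises included the mitotic kinase Aurka by 1.81 (SE 0.35), thymidine kinase Tk1 by 1.79 (SE 0.36), Birc5 by 2.34 (SE 0.47) and Ccnb1, cyclin B1, by 1.99 (SE 0.41). Of 20 genes of immune checkpoints and immunosuppression 13 rose and 1 fell (14 and 2 adjusted over the list alone), median 1.90 (camera adjusted p = 3.35e-07; adjusted p = 0.517 with an estimated correlation). Among the rises were Icos by 2.22 (SE 0.27), Cd274, which encodes PD-L1, by 2.33 (SE 0.31), Pdcd1lg2, which encodes PD-L2, by 2.58 (SE 0.36) and Cd200r1 by 2.06 (SE 0.29). The calls of Tk1 (1.31), Ccnb1 (0.085), Icos (0.664), Pdcd1lg2 (0.231) and Cd200r1 (0.0109) were lost after normexp background correction; Ccnb1, Pdcd1lg2 and Cd200r1 were well above background on 1 of 3 NNK arrays.

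Of 26 monocyte and tissue macrophage markers 15 rose and 2 fell (15 and 3 adjusted over the list alone), median 1.72 (camera adjusted p = 3.04e-07; adjusted p = 0.517 with an estimated correlation). The complement gene C1qc rose by 3.50 (SE 0.30), the Fc receptor Fcgr1 by 3.45 (SE 0.35), the chemokine receptor Ccr2 by 2.50 (SE 0.26), and Cd5l was at least 6.59-fold higher, a call lost after normexp background correction (0.45, adjusted p = 0.843). Of 27 T cell markers 12 rose and 1 fell (16 and 1 adjusted over the list alone), median 1.01 (camera adjusted p = 1.02e-06; adjusted p = 0.517 with an estimated correlation). Examples were Cd5 at 2.65 (SE 0.33), Lat at 2.65 (SE 0.33), Cd6 at 2.76 (SE 0.35) and Thy1 at 2.82 (SE 0.36). Of 19 dendritic cell and MHC class II genes 12 rose and 1 fell (14 and 2 adjusted over the list alone), median 1.28 (camera adjusted p = 1.34e-06; adjusted p = 0.517 with an estimated correlation). These included H2-Oa at 2.77 (SE 0.31) and H2-Ab1 at 2.28 (SE 0.29), which serve antigen presentation. B cell markers (8 of 23 rose, none fell, the same counts adjusted over the list alone; median 0.853) and plasma cell and immunoglobulin genes (6 of 16 rose and 1 fell, 7 and 1 adjusted over the list alone; median 0.927) had camera adjusted p of 4.03e-05 and 0.000639, and adjusted p = 0.572 and 0.517 with an estimated correlation. Cd72 rose by 3.67 (SE 0.52) and Jchain, the joining chain of secreted antibodies, by 4.00 (SE 0.48).

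Chemokines (10 of 26 rose, 1 fell; 13 and 1 adjusted over the list alone) had a median of 1.33 (camera adjusted p = 5.82e-05; adjusted p = 0.706 with an estimated correlation). Examples were Ccl19 at 4.38 (SE 0.41) and Ccl8 at 4.28 (SE 0.53). LPS sensing and NF-kB genes (6 of 22 rose, 1 fell; 10 and 2 adjusted over the list alone; median 0.658, camera adjusted p = 0.000272; adjusted p = 0.519 with an estimated correlation) were called up. They included Nfkbiz at 2.08 (SE 0.31) and the receptor Tlr1 at 1.79 (SE 0.30). Inflammatory cytokines (6 of 21 rose, none fell, the same counts adjusted over the list alone; median 0.266, camera adjusted p = 0.00252; adjusted p = 0.517 with an estimated correlation) were called up too. Members were lymphotoxin beta, Ltb, at 3.34 (SE 0.32), Lta at 2.50 (SE 0.28), and Il17a, at least 4.95-fold higher. Acute phase and secreted defence genes (6 of 21 rose, 1 fell; 7 and 1 adjusted over the list alone; median 0.981, camera adjusted p = 0.0064; adjusted p = 0.826 with an estimated correlation) were called up as well. Pigr, which carries antibody across epithelium, rose by 4.20 (SE 0.58). Cytotoxic and natural killer markers (5 of 16 rose, none fell, the same counts adjusted over the list alone; median 0.321, camera adjusted p = 0.0157; adjusted p = 0.826 with an estimated correlation) were the last list called up. Il2rb rose by 2.51 (SE 0.30). The neutrophil list (3 of 23 rose, 2 fell, median 0.196, camera adjusted p = 0.392) and the alveolar macrophage list (6 of 22 rose, none fell, median 0.228, camera adjusted p = 0.17) were not called. Il1r2 rose by 2.25 (SE 0.49) but had a log2 change of -0.0078 after normexp background correction and was well above background on 1 of 3 NNK arrays. Marco, a scavenger receptor, rose by 2.34 (SE 0.65) and lost its call without NNK 2, NNK 5, LPS/NNK 3 or LPS/NNK 6. Normexp ended the calls of Marco (1.42), Nfkbiz (1.22), Tlr1 (0.62), Lta (1.07) and Il17a (0.363) and of the cytotoxic list (median -0.0274, adjusted p = 0.137). The acute phase list lost its call without LPS/NNK 2 (adjusted p = 0.0876).

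Markers of endothelium (none of 26 rose, 5 fell, 7 adjusted over the list alone; median -0.51, camera adjusted p = 0.0189; adjusted p = 0.519 with an estimated correlation) were called down. The gap junction gene Gja5 fell by 2.40 (SE 0.35) and Nos3, endothelial nitric oxide synthase, fell by 1.51 (SE 0.32). Alveolar type 1 markers (none of 19 rose, 2 fell, the same counts adjusted over the list alone; median -0.532, camera adjusted p = 0.0218; adjusted p = 0.572 with an estimated correlation) were also called down. Scnn1b fell by 1.08 (SE 0.28). Clock and immediate-early genes (1 of 27 rose, 6 fell, 1 and 7 adjusted over the list alone; median -0.401, camera adjusted p = 0.0248; adjusted p = 0.572 with an estimated correlation) were called down as well. Cry2 fell by 1.49 (SE 0.26) and Per1 fell by 1.93 (SE 0.45). In the list of blood, heart, fat and thymus markers, tissues that can be sampled with lung, none of 18 rose and 7 fell (1 and 8 adjusted over the list alone; median -1.19, camera adjusted p = 0.00366; adjusted p = 0.755 with an estimated correlation). Ckm fell by 1.98 (SE 0.40), the muscle gene Myl4 by 2.04 (SE 0.42) and the erythroid gene Alas2 by 1.58 (SE 0.34). Not called by camera were alveolar type 2 markers (5 of 23 fell, adjusted p = 0.135) and club, goblet and basal markers (1 of 23 rose and 5 fell, adjusted p = 0.709). Sftpb, a surfactant protein gene, fell by 1.69 (SE 0.34) and the club cell gene Scgb1a1 fell by 1.41 (SE 0.29). Nor were ciliated cell markers (3 of 16 fell, adjusted p = 0.0729), mast cell, basophil, eosinophil and type 2 genes (1 of 12 fell, adjusted p = 0.211), or fibroblast and matrix genes (5 of 30 rose and 2 fell, adjusted p = 0.599). Mmp14, a matrix protease, rose by 2.64 (SE 0.31). The last lists not called were p53 targets (1 of 27 rose and 3 fell, adjusted p = 0.998), xenobiotic metabolism genes (4 of 38 rose and 7 fell, adjusted p = 0.25) and MAPK output and lung tumour genes (6 of 32 fell, adjusted p = 0.144). Of these lists and the neutrophil and alveolar macrophage lists, the counts adjusted over the list alone differed for neutrophils (5 rose), the mast cell list (none fell), p53 targets (none rose, 2 fell), xenobiotic metabolism (8 fell) and MAPK output (1 rose, 9 fell). Among the genes named in this paragraph only Gja5 and Mmp14 kept their call after normexp, which gave Nos3 -0.945, Scnn1b -0.681, Cry2 -0.982, Per1 -1.56, Ckm -1.07, Myl4 -1.56, Alas2 -1.17, Sftpb -1.35 and Scgb1a1 -1.05. Scnn1b lost its call without NNK 2, NNK 3, LPS/NNK 3 or LPS/NNK 6 and with the slide as a fixed effect, and Per1 without NNK 3, LPS/NNK 3 or LPS/NNK 6. The alveolar type 1 list was lost under normexp (adjusted p = 0.411), without NNK 3 (0.0667) and without LPS/NNK 2 (0.101), and the endothelial list under normexp (0.312) and without LPS/NNK 2 (0.0918). The clock list was lost without NNK 5 (0.0797) and without LPS/NNK 6 (0.0706). The alveolar type 2 list was called down after quantile normalization (adjusted p = 0.0187), after cyclic loess (0.0115) and without NNK 2 (0.0135). The ciliated list was called down without NNK 5 (0.0408) or LPS/NNK 3 (0.0145). Neither was called with an estimated correlation.

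**Figure D4:**
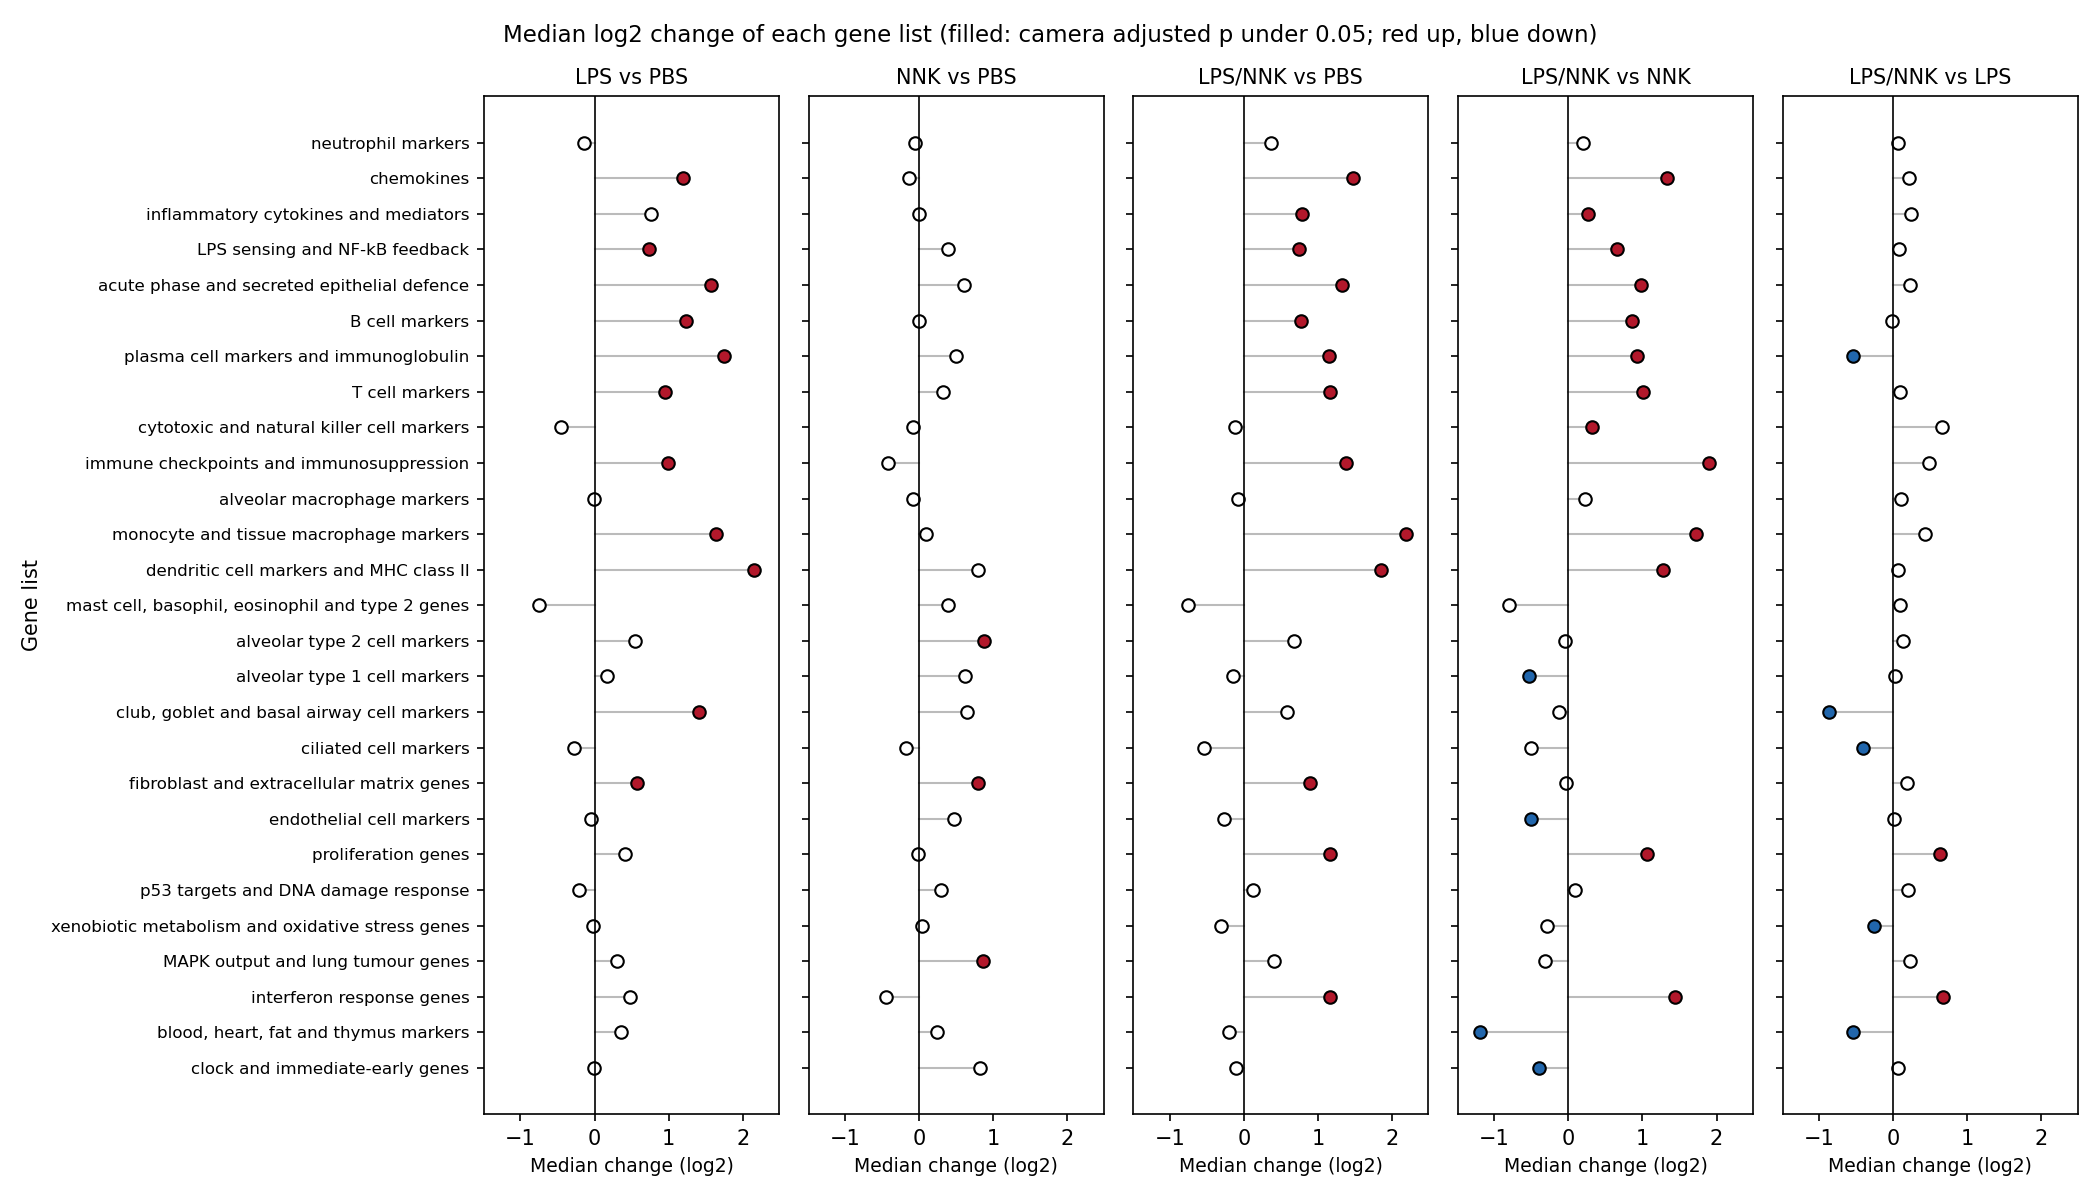
Median log2 fold change of the measured genes of each of the 27 lists (horizontal axis, 1 panel per group comparison; the lists are on the vertical axis). Filled points have a camera adjusted p under 0.05, red for up and blue for down; for LPS/NNK against NNK the medians reach 1.90 for immune checkpoints and -1.19 for blood, heart, fat and thymus markers.

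Camera with a preset correlation called 13 lists up and 4 down of 27 in this comparison. Fry, which asks whether a list moves on balance 1 way and does not compare it with other genes, called 14 of 27. Camera with an estimated correlation called 0, with 7 at an unadjusted p under 0.05. When the residuals of the arrays were regrouped 100 times with no group effect left in them, camera with the preset called a median of 8 lists (highest 16) in this comparison, and at least 1 list in 98 of the 100 regroupings; with an estimated correlation it did so in 2. Slides 6 and 7 held an array of each group (LPS/NNK 2 with NNK 3, and LPS/NNK 3 with NNK 5). Within them Cxcl9 differed by 5.19 and 7.45, Ifng by 4.37 and 5.01. The interferon list differed by a median of 1.6 and 2.33 and the blood, heart, fat and thymus list by -1.09 and -0.00611. With the slide as a fixed effect 2606 items changed and 103 of the 115 named genes called here kept their call. The interferon median was 1.57 (camera adjusted p = 3.78e-18) and that of proliferation 0.826 (adjusted p = 6.84e-10), both with the preset correlation. No correlation between genes was estimated in this fit. The lists of blood, heart, fat and thymus (adjusted p = 0.0642) and alveolar type 1 (adjusted p = 0.0515) were no longer called, and MAPK output and lung tumour genes were called down (median -0.479, adjusted p = 0.0435; adjusted p = 0.928 with an estimated correlation and no slide effect). After normexp background correction 353 items changed, 333 higher and 20 lower, and 43 of those 115 genes kept their call.

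LPS against PBS asks what weekly endotoxin alone left in the lung. Glycam1, a ligand for lymphocyte homing made in specialised venules, rose by 7.55 (SE 0.85, adjusted p = 2.64e-05), Cd177, a neutrophil surface protein, by 5.23 (SE 0.56, adjusted p = 2.11e-05) and Dnase1l3, a nuclease of macrophages and dendritic cells, by 5.21 (SE 0.40, adjusted p = 2.65e-06). Dmbt1, a secreted defence protein, rose by 5.52 (SE 1.02), Gp2 by 5.43 (SE 1.02) and Creg2 by 5.10 (SE 0.47), while Tspan10 was at least 15.3-fold and Oosp1 at least 24.7-fold higher. Xdh, xanthine dehydrogenase, fell by 4.04 (SE 0.33, adjusted p = 3.82e-06), Cd209b by 4.26 (SE 0.77), and Tatdn2 by 3.97 (SE 0.41), while Eml6, Sin3b, Adamts4, Kif12 and Gria3 were at least 10.9-, 5.39-, 6.16-, 6.55- and 6.24-fold lower. In all 9 treated arrays the levels of Sin3b, Kif12, Eml6, Tatdn2 and Xdh lay below those in PBS, in NNK as in LPS. The calls of Sin3b (-0.96), Adamts4 (-1.31), Kif12 (-1.04) and Gria3 (-0.893) were lost after normexp background correction, and that of Gp2 with PBS 3 as the only PBS array (3.27, adjusted p = 0.0656). Glycam1 and Creg2 were well above background on 1 of 3 PBS arrays and Dmbt1 and Gp2 on 2 of 3, Cd209b and Tatdn2 on 1 of 3 LPS arrays.

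Plasma cell and immunoglobulin genes rose in 12 of 16 cases and fell in 1 (13 and 1 adjusted over the list alone), median 1.75 (camera adjusted p = 2.57e-05; adjusted p = 0.517 with an estimated correlation). The rises included Derl3 by 5.08 (SE 0.25), Mzb1 by 3.70 (SE 0.31) and Tnfrsf17, a receptor of plasma cells, by 3.96 (SE 0.37). Of 19 dendritic cell and MHC class II genes 14 rose and 2 fell, the same counts adjusted over the list alone, median 2.15 (camera adjusted p = 4.03e-05; adjusted p = 0.519 with an estimated correlation). Among the rises were H2-Ab1 by 3.22 (SE 0.29) and Itgae by 2.67 (SE 0.21). Of 27 T cell markers 16 rose and 2 fell (17 and 2 adjusted over the list alone), median 0.956 (camera adjusted p = 0.000578; adjusted p = 0.519 with an estimated correlation). Examples were Cd5 at 3.23 (SE 0.33) and Thy1 at 3.37 (SE 0.36). Of 26 monocyte and tissue macrophage markers 15 rose and 4 fell, the same counts adjusted over the list alone, median 1.64 (camera adjusted p = 0.000694; adjusted p = 0.572 with an estimated correlation). Examples were the complement genes C1qa at 4.30 (SE 0.37), C1qb at 3.97 (SE 0.32) and C1qc at 4.32 (SE 0.30). Of 23 B cell markers 13 rose and 1 fell, the same counts adjusted over the list alone, median 1.23 (camera adjusted p = 0.00175; adjusted p = 0.755 with an estimated correlation). Examples were Blnk at 2.94 (SE 0.28) and Cd22 at 2.25 (SE 0.30).

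Camera also called 6 further lists up, with adjusted p of 0.0064 to 0.0285 and adjusted p of 0.621 to 0.826 with an estimated correlation. Adjusted over the list alone the counts were the same, except 12 that rose among immune checkpoints. The 6 lists included acute phase and secreted defence (11 of 21 rose), LPS sensing and NF-kB (12 of 22 rose and 2 fell) and chemokines (13 of 26 rose and 1 fell). Lrg1 rose by 3.45 (SE 0.41), Nfkb2 by 2.40 (SE 0.31) and Ccl19 by 4.26 (SE 0.41). The other 3 were immune checkpoints (11 of 20 rose and 2 fell), club, goblet and basal markers (14 of 23 rose and 3 fell) and fibroblast and matrix genes (13 of 30 rose and 3 fell). Lag3 rose by 4.45 (SE 0.34), Scgb3a1, a secretoglobin, by 3.15 (SE 0.52) and Col1a2, a collagen chain, by 2.14 (SE 0.36). Interferon response genes (12 of 35 rose and 5 fell, median 0.484) had a camera adjusted p of 0.103 and proliferation genes (13 of 34 rose and 4 fell, median 0.407) 0.0611. Some alternatives called them up. Proliferation passed after quantile normalization (0.0302) and cyclic loess (0.0231) and without PBS 1 (0.000748) or LPS 6 (0.0199). Interferon response passed without PBS 1 (0.0497), PBS 3 (0.02) or LPS 6 (0.0235). Neither was called after normexp or with an estimated correlation. In the blood, heart, fat and thymus list 3 of 18 rose; Hba-a1, a haemoglobin gene, rose by 1.21 (SE 0.33) but had a log2 change of -0.34 after quantile normalization and after cyclic loess, and lost its call also under normexp (1.12), with the slide series as a term and with PBS 3 alone. Cpa3, a mast cell protease, was at least 1.38-fold lower, with a log2 change of 0.12 after normexp background correction, and lost its call with the slide series as a term. The club, goblet and basal list was not called after quantile normalization (adjusted p = 0.0508) or with PBS 3 alone (0.07), and the matrix list after normexp (0.187), quantile normalization (0.291) or cyclic loess (0.396).

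In total 12240 items changed between LPS and PBS, 5695 higher and 6545 lower; 7189 were named genes, 4347 higher and 2842 lower. Arrays of the groups did not overlap for 62.5% of items, where chance gives 10%. The PBS arrays stood apart from every treated array, as the principal components show, and the LPS arrays lay alone on slides 2, 3 and 4, so that slide and treatment could not be separated here. Along mean signal the median change ran from -1.11 to 0.74 over 8 groups of genes from dim to bright. After normexp background correction 4124 items changed, 2638 higher and 1486 lower. With no filter on dim probes 19478 changed, 12985 higher and 6493 lower. Rises outnumbered falls under both, but neither count can decide which direction prevails. Signal not above background lay lower on PBS 3 than on the LPS arrays after scaling. Ddx3y was at -8.1 against -6.68 to -6.24, and Uty at -8.03 against -6.61 to -6.2. Probes not above background can thus count as rises without the filter, and normexp adds a constant offset to arrays of unequal brightness. With the slide series (batch of slides) as a term LPS was in effect set against PBS 2 alone, so the term is no separate adjustment for the batch. PBS 2 also differed from all other arrays in the day of its scan. The median change of all items was -0.0782 with this term and -0.0453 with PBS 3 as the only PBS array.

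NNK against PBS asks what the carcinogen alone left in the lung, set against mice that by the labels received PBS for 16 weeks. Age at death may differ between these groups too. Npy, neuropeptide Y, was at least 27.3-fold and Serpinb5, a member of the serpin family, at least 7.15-fold higher in NNK. Ltf, lactoferrin, rose by 4.58 (SE 0.98, adjusted p = 0.00216), Dmbt1 by 6.20 (SE 1.02, adjusted p = 0.000524), Cdhr1 by 5.26 (SE 1.01), Cdk5r2 by 4.96 (SE 0.92) and the synaptotagmin gene Syt10 by 4.94 (SE 0.51). Dlk1, a Notch ligand homologue of fetal tissue, rose by 7.55 (SE 1.89, adjusted p = 0.00542), but NNK 2 and PBS 3 on the same slide differed by 0.901, and with the slide as a fixed effect its adjusted p was 0.0708. Xdh fell by 3.54 (SE 0.33, adjusted p = 5.14e-05), the matrix gene Dpt by 3.30 (SE 0.53), Arl6ip5 by 3.72 (SE 0.23), Creb3l3 by 3.83 (SE 0.29), Tatdn2 by 3.89 (SE 0.41) and Eml6 by 3.67 (SE 0.31), and Sin3b and Kif12 were at least 8.02- and 9.74-fold lower. With the slide as a fixed effect Ltf was at 2.61, Dmbt1 at 3.99 and Cdhr1 at 3.02 (adjusted p = 0.00964, 0.0142 and 0.00552), and with PBS 3 as the only PBS array Ltf (2.39), Cdhr1 (2.09) and Dlk1 (7.42) lost their call (adjusted p = 0.158, 0.0708 and 0.0857). Normexp ended the calls of Creb3l3 (-0.922), Eml6 (-0.877), Sin3b (-0.0112) and Kif12 (-0.205). Cdhr1 was well above background on 1 of 3 PBS arrays, Dmbt1 and Dlk1 on 2 of 3, and Creb3l3 on 2 of 3 NNK arrays.

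Of 23 alveolar type 2 cell markers 13 rose and 1 fell (15 and 1 adjusted over the list alone), median 0.874 (camera adjusted p = 0.00654; adjusted p = 0.519 with an estimated correlation). The rises included the fatty acid synthase Fasn by 2.36 (SE 0.30), the surfactant lipid transporter Abca3 by 1.95 (SE 0.30) and Sftpb by 1.70 (SE 0.34). Of 32 MAPK output and lung tumour genes 16 rose and 2 fell (17 and 2 adjusted over the list alone), median 0.863 (camera adjusted p = 0.00838; adjusted p = 0.826 with an estimated correlation). Among the rises were the receptor kinases Erbb2 by 1.44 (SE 0.23) and Epha2 by 1.93 (SE 0.36). Of 30 fibroblast and matrix genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), median 0.792 (camera adjusted p = 0.0112; adjusted p = 0.766 with an estimated correlation). Examples were the collagen chains Col15a1 at 2.40 (SE 0.27) and Col1a1 at 2.10 (SE 0.38). Within slide 5 these lists differed by a median of 0.547, 0.609 and 1.14 in that order, and with the slide as a fixed effect their medians were 0.776, 0.646 and 0.768 (camera adjusted p = 0.0159, 0.00835 and 0.011). After normexp background correction the median of all items was 0.555, those of the alveolar type 2 and matrix lists were 0.366 and 0.364, and camera placed both lists below other genes (adjusted p = 0.892 and 0.953). The MAPK list (adjusted p = 0.202), Sftpb (1.07) and Epha2 (1.25) lost their call there. In all, normexp left 5 lists called, each down and none of them called when no alternative was applied. They were interferon response (median -0.693, adjusted p = 3.23e-07), xenobiotic metabolism (-0.107, adjusted p = 0.00058), endothelial (-0.109, adjusted p = 0.00315), alveolar type 1 (-0.0463, adjusted p = 0.012) and alveolar macrophage markers (-0.189, adjusted p = 0.0133); with an estimated correlation and without normexp their adjusted p was 0.919 to 0.997. The alveolar type 2 and matrix lists were not called after quantile normalization (adjusted p = 0.588 and 0.136) or cyclic loess (0.714 and 0.231). Interferon response genes (3 of 35 rose and 13 fell, median -0.454, camera adjusted p = 0.0798; adjusted p = 0.928 with an estimated correlation) included Ifi205, which fell by 1.81 (SE 0.31). This list was also called down after quantile normalization (median -0.966, adjusted p = 0.0338) and cyclic loess (-0.885, adjusted p = 0.0231). The same held with the slide as a fixed effect (median -0.78, adjusted p = 0.000193) and without PBS 2 (0.00224), NNK 2 (0.0383) or NNK 3 (0.0442). No correlation was estimated in these fits. Among p53 targets (8 of 27 rose and 7 fell, camera adjusted p = 0.657) Phlda3 rose by 2.04 (SE 0.28) and Zmat3 by 1.79 (SE 0.34).

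In total 11259 items changed between NNK and PBS, 6076 higher and 5183 lower; 6928 were named genes, 4517 higher and 2411 lower. Arrays of the groups did not overlap for 67.6% of items, where chance gives 10%. The PBS arrays stood apart from every treated array here too. Along mean signal the median change ran from -0.82 to 0.78. With the slide as a fixed effect 6638 items changed and 105 of the 123 named genes called here kept their call, and with PBS 3 as the only PBS array 4295 items changed. With no filter on dim probes 17557 changed, 12354 higher and 5203 lower. As in LPS against PBS, this count and that after normexp cannot decide which direction prevails. Falls outnumbered rises after quantile normalization (5673 higher and 5719 lower) and cyclic loess (5238 higher and 5845 lower). After normexp background correction 8012 changed, 6591 higher and 1421 lower, of which 4609 were called in the same direction without it, while 71 of the 123 kept their call and 10 had the opposite sign.

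LPS/NNK against PBS asks what both treatments together left in the lung. H2ac4, a histone gene, rose by 7.05 (SE 1.06, adjusted p = 0.000133), Glycam1 by 7.05 (SE 0.85, adjusted p = 3.06e-05), Ubd by 6.64 (SE 0.88, adjusted p = 5.66e-05), Dnase1l3 by 5.95 (SE 0.40) and Gpr162 by 5.65 (SE 0.30). Spink5, a protease inhibitor of epithelium, was at least 18.4-fold and Tspan10 at least 14.3-fold higher. Slc4a7, a bicarbonate transporter, rose by 5.88 (SE 1.05), with 2 of its 3 probes in that direction. Cd209b fell by 4.93 (SE 0.77), Xdh by 4.38 (SE 0.33), Rgs18 by 3.72 (SE 0.36), Tatdn2 by 4.00 (SE 0.41), Cst8 by 4.00 (SE 0.59) and Eml6 by 3.67 (SE 0.31), with adjusted p from 2.29e-06 to 0.000186, and Sin3b and Kif12 were at least 6.76- and 8.21-fold lower. The calls of Eml6 (-1.15), Sin3b (-0.35) and Kif12 (-0.503) were lost after normexp background correction. On the PBS arrays Glycam1 was well above background on 1 of 3 and Ubd on 2 of 3, and on the LPS/NNK arrays Cd209b and Eml6 were on 1 of 3 and Tatdn2 and Cst8 on 2 of 3.

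Of 26 monocyte and tissue macrophage markers 16 rose and 3 fell, the same counts adjusted over the list alone, median 2.19 (camera adjusted p = 0.000122; adjusted p = 0.519 with an estimated correlation). Examples were C1qc at 5.29 (SE 0.30) and Cx3cr1, the fractalkine receptor, at 3.35 (SE 0.30). Of 19 dendritic cell and MHC class II genes 14 rose and 3 fell, the same counts adjusted over the list alone, median 1.85 (camera adjusted p = 0.000259; adjusted p = 0.519 with an estimated correlation). An example was Cd74, the invariant chain, at 3.31 (SE 0.29). Of 34 proliferation genes 22 rose and none fell, the same counts adjusted over the list alone, median 1.17 (camera adjusted p = 0.00116; adjusted p = 0.826 with an estimated correlation). Examples were Cdc20 at 2.70 (SE 0.30) and the kinase Plk1 at 2.55 (SE 0.34). Of 20 genes of immune checkpoints and immunosuppression 14 rose and 2 fell, the same counts adjusted over the list alone, median 1.38 (camera adjusted p = 0.00154; adjusted p = 0.519 with an estimated correlation). Examples were Lag3 at 5.02 (SE 0.34) and Pdcd1, which encodes PD-1, at 4.65 (SE 0.62). Of 27 T cell markers 16 rose and 1 fell, the same counts adjusted over the list alone, median 1.16 (camera adjusted p = 0.00144; adjusted p = 0.519 with an estimated correlation). An example was Thy1 at 4.42 (SE 0.36).

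Camera called 8 further lists up, with adjusted p of 0.00381 to 0.0461 and adjusted p of 0.519 to 0.835 with an estimated correlation. Adjusted over the list alone the counts were the same, except 2 that fell among interferon response genes and 18 that rose among matrix genes. The 8 lists included plasma cell and immunoglobulin (10 of 16 rose), interferon response (19 of 35 rose and 1 fell), chemokines (11 of 26 rose and 1 fell) and LPS sensing and NF-kB (10 of 22 rose and 1 fell). Jchain rose by 4.46 (SE 0.48), the immunoproteasome gene Psmb8 by 3.14 (SE 0.36), Ccl8 by 4.97 (SE 0.53) and Bcl3 by 2.97 (SE 0.48). The other 4 were fibroblast and matrix (17 of 30 rose and 3 fell), acute phase (10 of 21 rose), B cell (10 of 23 rose and 2 fell) and inflammatory cytokines (10 of 21 rose and 3 fell). Mmp14 rose by 3.50 (SE 0.31), Lrg1 by 4.13 (SE 0.41) and Cd72 by 3.42 (SE 0.52), and Il17a was at least 11.1-fold higher. Among lists not called, Sntn, a ciliated cell gene, fell by 1.86 (SE 0.30) but had a log2 change of 0.032 after normexp background correction and was well above background on 2 of 3 LPS/NNK arrays. In all, 12034 items changed, 6102 higher and 5932 lower; 7053 were named genes, 4481 higher and 2572 lower. Arrays of the groups did not overlap for 61.9% of items, where chance gives 10%. PBS arrays stood apart from all treated arrays, and along mean signal the median change ran from -1.10 to 0.86. Slide 8 held LPS/NNK 6 and PBS 1, which differed by 7.99 for Glycam1, by a median of 1.93 for the monocyte list and by 0.385 for proliferation genes. With the slide as a fixed effect 8723 items changed, 123 of the 124 named genes called here kept their call, and the medians were 2.04 for the monocyte list (camera adjusted p = 0.000247) and 0.917 for proliferation (adjusted p = 0.00577). It ended the calls of the lists of LPS sensing and NF-kB (adjusted p = 0.0673), acute phase (adjusted p = 0.258; median within slide 8 -0.289) and inflammatory cytokines (adjusted p = 0.106). Normexp ended those of interferon response (adjusted p = 0.165), LPS sensing and NF-kB (0.235), matrix (0.27), acute phase (0.11) and inflammatory cytokines (0.0835). Normexp placed the median of all items at 0.532, so a list that camera calls down against other genes need not fall. It called 5 lists down that were not called when no alternative was applied (camera adjusted p = 0.000222 to 0.0205, and 0.916 to 0.979 with an estimated correlation and without normexp). They were alveolar type 1 (median -0.335), endothelial (-0.237), ciliated (-0.102), xenobiotic metabolism (0.0224), and blood, heart, fat and thymus (-0.281). Of these, alveolar type 1, endothelial and xenobiotic metabolism were also called down after quantile normalization (adjusted p = 0.00978, 0.0146 and 0.0397) and cyclic loess (0.00469, 0.00961 and 0.0284). Quantile normalization and cyclic loess ended the calls of acute phase (0.0549 and 0.0536) and matrix (0.142 and 0.211). The B cell list was not called without PBS 1 (0.0544) or LPS/NNK 2 (0.0815), acute phase without PBS 2 (0.0547), and inflammatory cytokines without PBS 2 (0.079), PBS 3 (0.0577), LPS/NNK 2 (0.0715) or LPS/NNK 6 (0.0512). Inflammatory cytokines were not called with the slide series as a term either (0.0711), which here amounts to leaving out PBS 2. After normexp background correction 6470 items changed, 5175 higher and 1295 lower, and with no filter on dim probes 18656, 12728 higher and 5928 lower. As in LPS against PBS, neither count can decide which direction prevails. Falls outnumbered rises after quantile normalization (5740 higher and 6381 lower) and cyclic loess (5619 higher and 6283 lower). With PBS 3 as the only PBS array 6615 changed.

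LPS/NNK against LPS asks what the carcinogen added in lungs also given endotoxin. Spink5 was at least 5.53-fold (adjusted p = 8.25e-06), Mug1 at least 1.39-fold, Rgmb at least 3.53-fold and Hacl1 at least 2.4-fold higher. Slc4a7 rose by 4.86 (SE 1.05, adjusted p = 0.0259), Tnfsf12, a cytokine of the TNF family, by 2.72 (SE 0.58), Hrg, a plasma glycoprotein, by 2.56 (SE 0.37) and Galnt5 by 2.51 (SE 0.37). Entpd8 fell by 2.60 (SE 0.41), Mup1 by 2.56 (SE 0.63), Tcte1 by 2.34 (SE 0.59), Hjv by 2.29 (SE 0.48), Mindy4 by 2.28 (SE 0.55), Adrb1 by 2.19 (SE 0.49) and Stk40 by 2.14 (SE 0.52). Ifng rose by 1.78 (SE 0.43, adjusted p = 0.0387) and Areg, a ligand of the EGF receptor, by 2.33 (SE 0.46, adjusted p = 0.0195). Of the LPS/NNK arrays, Entpd8, Mup1, Tcte1, Hjv and Mindy4 were well above background on 1 of 3 and Stk40 on 2 of 3, and Entpd8 was at -0.0185 after normexp background correction.

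Of 23 club, goblet and basal airway markers 1 rose and 3 fell (1 and 5 adjusted over the list alone), median -0.861 (camera adjusted p = 4.03e-05; adjusted p = 0.62 with an estimated correlation). Scgb1a1, the club cell secretory protein, fell by 1.69 (SE 0.29), Cckar by 1.47 (SE 0.26) and Chad by 1.76 (SE 0.43), while Krt14, a basal keratin, rose by 1.45 (SE 0.32). Of 16 ciliated cell markers none passed (3 fell adjusted over the list alone), median -0.402 (camera adjusted p = 0.00442; adjusted p = 0.755 with an estimated correlation). An example was Dnah5 at -0.94 (SE 0.27). Of 16 plasma cell and immunoglobulin genes 2 fell (4 adjusted over the list alone), median -0.546 (camera adjusted p = 0.0019; adjusted p = 0.517 with an estimated correlation). Xbp1 fell by 1.51 (SE 0.30) and Tnfrsf17 by 1.69 (SE 0.37). Of 34 proliferation genes 1 rose (6 adjusted over the list alone), Cenpf by 1.79 (SE 0.46), with a list median of 0.632 (camera adjusted p = 0.0064; adjusted p = 0.835 with an estimated correlation), and of 35 interferon response genes 1 rose (0 adjusted over the list alone), Ifi205 by 1.21 (SE 0.31), with a median of 0.674 (camera adjusted p = 0.00862; adjusted p = 0.845 with an estimated correlation). Both turned with the slide series as a term, which 1 PBS array alone separates from the groups, to -0.19 for proliferation (adjusted p = 0.0599) and -0.494 for interferon response (called down, adjusted p = 0.00266). The xenobiotic metabolism list (1 of 38 fell, 2 adjusted over the list alone, median -0.251, camera adjusted p = 0.0132; adjusted p = 0.572 with an estimated correlation) and the blood, heart, fat and thymus list (1 of 18 rose and 2 fell, 1 and 5 adjusted over the list alone, median -0.547, camera adjusted p = 0.00295; adjusted p = 0.755 with an estimated correlation) were called down. Ckm fell by 1.77 (SE 0.40). The proliferation list lost its call without LPS 6 (adjusted p = 0.107), the xenobiotic list without LPS 1 (0.158) or LPS/NNK 2 (0.182), and the interferon list without LPS 6 (0.326) or LPS/NNK 2 (0.171) and after normexp (0.127).

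In total 898 items changed between LPS/NNK and LPS, 622 higher and 276 lower; 473 were named genes, 297 higher and 176 lower. Arrays of the groups did not overlap for 20.9% of items, where chance gives 10%. No slide held arrays of both groups. The count moved when single arrays were left out, which also leaves fewer arrays to detect a change. It was 296 without LPS 1, 359 without LPS 5, 569 without LPS 6, 78 without LPS/NNK 3 and 111 without LPS/NNK 6. The count rose only without LPS/NNK 2, to 4825, and another split of these 6 arrays gave 3054. It was 1 with the slide series as a term (1628 at an unadjusted p under 0.05) and 0 in limma after normexp background correction (1522 at an unadjusted p under 0.05), where 0 of the 38 named genes called here kept their call.

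The interaction of LPS and NNK asks whether the change from LPS differed between mice with and without the carcinogen. It is the change LPS/NNK minus NNK less the change LPS minus PBS, so a positive term means a change from LPS that was higher with NNK. Among interferon response genes 14 of 35 had a positive term and none a negative one (15 and 1 adjusted over the list alone), median 0.83 (camera adjusted p = 0.00648; adjusted p = 0.835 with an estimated correlation). With the slide series as a term the median was 0.496 and the call was lost (adjusted p = 0.353). Examples were Ifi205 at 3.02 (SE 0.44), Ifi204 at 2.03 (SE 0.35) and Ifit3 at 1.99 (SE 0.38). Plasma cell and immunoglobulin genes had a positive term in 1 and a negative one in 10 of 16 (1 and 11 adjusted over the list alone), median -1.24 (camera adjusted p = 0.00819; adjusted p = 0.519 with an estimated correlation). Examples were Sdc1 at -1.96 (SE 0.33) and Derl3 at -1.86 (SE 0.35). Alveolar type 2 markers (1 positive and 8 negative of 23, 1 and 9 adjusted over the list alone) had a median of -0.818 (camera adjusted p = 0.00895; adjusted p = 0.519 with an estimated correlation). Examples were Sftpb at -2.74 (SE 0.47) and Fasn at -2.45 (SE 0.43). Club, goblet and basal markers (2 positive and 8 negative of 23, 2 and 10 adjusted over the list alone) had a median of -1.38 (camera adjusted p = 0.0105; adjusted p = 0.826 with an estimated correlation). An example was the mucin gene Muc1 at -4.42 (SE 0.76). Blood, heart, fat and thymus markers (1 positive and 7 negative of 18, 1 and 8 adjusted over the list alone) had a median of -1.63 (camera adjusted p = 0.0107; adjusted p = 0.826 with an estimated correlation). An example was Ckm at -3.01 (SE 0.57). The alveolar type 2 list was not called after normexp (median -0.339, adjusted p = 0.437), quantile normalization (-0.475, adjusted p = 0.494) or cyclic loess (-0.435, adjusted p = 0.481). Nor was the blood, heart, fat and thymus list under these (adjusted p = 0.0679, 0.0746 and 0.0548) or with PBS 3 as the only PBS array (0.149), or the club, goblet and basal list without LPS/NNK 6 (0.0716). Of the genes named in this paragraph only Muc1 kept its call after normexp.

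The largest negative terms were those of Fthl17e (-6.85, SE 1.16), Dmbt1 (-6.30, SE 1.44), Cdhr1 (-5.96, SE 1.43), Ltf (-5.27, SE 1.38), Arid5b (-5.19, SE 1.03), Cdk5r2 (-5.18, SE 1.30), Gp2 (-5.17, SE 1.45) and Cacna1h (-5.15, SE 0.87). Each was higher in all 3 treated groups than in PBS on average. Positive terms included those of Trim55 (4.18, SE 1.06), Taf15 (4.11, SE 0.44), Ddx25 (3.90, SE 0.97), Tatdn2 (3.86, SE 0.59) and Gbp8 (3.83, SE 1.04). Trim12c, Eml6 and Sin3b had a positive term too, with neither size nor rank, since Trim12c and Eml6 were not well above background on any LPS array and Sin3b on none of the 9 treated arrays. Ifng had a term of 2.70 (SE 0.61) and Cd177 of -5.11 (SE 0.80). Of the genes named in this paragraph only Fthl17e and Cd177 kept their call after normexp. Those of Dmbt1, Cdhr1, Ltf and Gp2 were also lost with PBS 3 as the only PBS array, and those of Cdk5r2, Trim55, Ddx25, Gbp8 and Ifng with the slide series as a term. Cdhr1 and Cacna1h were well above background on 1 of 3 PBS arrays and Dmbt1 and Gp2 on 2 of 3, Tatdn2 on 1 of 3 LPS arrays, and Cacna1h and Tatdn2 on 2 of 3 LPS/NNK arrays. In total 8460 items had a term at an adjusted p under 0.05, 4398 positive and 4062 negative. This count was 71 after normexp background correction, 13186 with no filter on dim probes (4226 positive and 8960 negative), 4616 with the slide series as a term and 2630 with PBS 3 as the only PBS array. The PBS arrays stood apart from all treated arrays. The term correlated across genes with NNK against PBS at r = -0.871 and with LPS against PBS at r = -0.799. It holds the arrays of both comparisons with opposite sign, so noise alone makes these values negative and they decide nothing. With LPS/NNK against PBS, where the noise of the shared arrays cancels, r was -0.524.

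Across the 21853 items, which are not independent replicates, the change from LPS without NNK correlated with that with NNK at Pearson r = 0.327 and Spearman rho = 0.171. Together 902 items were higher in both (451.1 if the calls were independent), 731 lower in both (611.6 if independent) and 590 changed in opposite directions. For NNK without and with LPS r was -0.0518 and rho -0.0722, and the sign of r was not stable. It was 0.00223 without NNK 2, 0.0205 without LPS/NNK 6 and 0.00541 with PBS 3 as the only PBS array, and -0.105 without NNK 5. Here 186 items were higher in both (172.9 if independent), 37 lower in both (65.46 if independent) and 226 in opposite directions. These pairs share no array. Changes of treated groups against the same PBS arrays correlated at 0.788 to 0.884. Pure noise gave 0.50 in 100 simulated draws, a value fixed by the shared PBS arrays, so it does not give the share of noise in these correlations. The covariance from shared PBS noise was 0.0594 to 0.0596 in these draws, against 1.18 to 1.58 observed. The draws hold no systematic difference of the PBS arrays. In 30 of the 162 list tests the median, the mean and the directions of camera and fry differed in sign. These were 7 for LPS against PBS, 6 for NNK against PBS, 3 for LPS/NNK against PBS, 2 for LPS/NNK against NNK, 10 for LPS/NNK against LPS and 2 for the interaction. Among them were the neutrophil list in LPS against PBS (median -0.139, mean 0.688), the cytotoxic list in LPS/NNK against PBS (median -0.119, mean 0.391), and fibroblast and matrix genes (median -0.0328, mean 0.0965) and p53 targets (median 0.0905, mean -0.0121) in LPS/NNK against NNK. None of these 30 was called by camera or fry. With genes not above background set to their bound, 6 of the called medians moved, the farthest from 0.777 to 0.901 (B cell, LPS/NNK against PBS), and none of them changed sign. Immune checkpoints in LPS/NNK against NNK went from 1.90 to 1.81 and club, goblet and basal markers in LPS/NNK against LPS from -0.861 to -0.778.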

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

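The tests of sex and slide for the PBS arrays, of the separation of the PBS arrays behind the interaction, of exchanged labels for LPS/NNK 2 and LPS 6, and of airway tissue and slide series were chosen only after their results were seen, and the slide series and cyclic loess are alternatives added then.

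The interaction term of LPS and NNK passed for 8460 items. Camera called 5 lists for it, none of them with an estimated correlation (adjusted p = 0.519 to 0.835), with these medians of the term over their measured genes: plasma cell and immunoglobulin genes at -1.24, alveolar type 2 markers at -0.818, club, goblet and basal markers at -1.38, interferon response genes at 0.83, and blood, heart, fat and thymus markers at -1.63. In 1 of 100 relabellings of the 12 arrays, the real one, as many items had a term, and the highest of the others gave 8012, but relabelling all 12 arrays also breaks up PBS. With the PBS arrays kept together and the labels of the 9 treated arrays drawn again, 5 of 100, the real one included, gave as many (median 4326, highest 8814), so the separation of the PBS arrays may account for the count. With 10 splits of 6 arrays a share under 0.05 cannot be had for the group comparisons. At least as many items as in the real split were found in 1 split for LPS against PBS (12240, highest other 0), 1 for NNK against PBS (11259, highest other 0), 1 for LPS/NNK against PBS (12034, highest other 0), 1 for LPS/NNK against NNK (3773, highest other 1) and 2 for LPS/NNK against LPS (898, highest other 3054). The split with 3054 set LPS 1, LPS 5 and LPS/NNK 2 against LPS 6, LPS/NNK 3 and LPS/NNK 6, over 3 times the real count, which points to a structure of these samples.

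The interaction shares its PBS arrays with the separation of PBS from all 9 treated arrays. The sex of PBS 1 and 2 does not account for the place of PBS 3: measured from this single array the shift of the treated arrays kept a slope across genes of at least 0.736 (27 splits of the treated arrays, highest 0.893) on the shift from PBS 1 and 2, where under 0.5 was needed. Slides alone do not give the whole separation in the NNK and LPS/NNK arrays, where a treated and a PBS array on the same slide kept slopes of 0.585 and 0.74. Each slope rests on 1 pair of arrays, so a share of the slide in the separation is not excluded. The position on the slide followed the group and stays open. Slides also stay open for the LPS arrays, since 0 slides held an LPS and a PBS array. A linear trend with array brightness does not give it: the slope within treated groups was 0.0785 (SE 0.0284) where -0.658 was needed for the brightness gap of 1.52. No treated array was as bright as a PBS array, so an effect of brightness or background that is not linear could not be tested and stays open. A difference in the handling or labelling of RNA between PBS and treated samples may remain, as may a biological effect common to the treatments, which the design names; neither was tested.

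LPS/NNK 2 correlated with the LPS arrays at r = 0.9685 to 0.9804 and with LPS/NNK 3 and 6 at 0.9648 to 0.9714, and its removal raised the count of LPS/NNK against LPS to 4825. On the axis from LPS (0) to LPS/NNK 3 and 6 (1) it lay at 0.328 to 0.349, against 0.0335, 0.109 and 0.363 for held-out LPS arrays, a smallest difference of -0.0341, so an LPS array under a wrong label stays open. Over 6860 genes LPS 6 lay at a median of 0.371 and LPS/NNK 2 at 0.269; exchanged labels would need LPS 6 above 0.5, but the SD of held-out LPS positions, 0.172, leaves this open, and the rule of this test was changed after its first run, which used a bootstrap over genes of the same array and would have excluded the exchange. Brightness also stays open: the lowest correlation of LPS/NNK 2 with an LPS array minus the highest with LPS/NNK 3 or 6 was -0.00286 before and -0.0024 after cyclic loess, so the correction moved it little, but the ranges overlap both times. A mouse that responded less to NNK may account for it as well, which was not tested. LPS/NNK 2 lay at position 4 of a slide of the second series, like LPS/NNK 3 and 6. LPS 6 lay at position 2 of a slide of the first series, like LPS 1 and 5. This layout argues against arrays exchanged after they were run, but not against samples exchanged before.

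Camera called airway markers down in LPS/NNK against LPS, for club, goblet and basal cells (median -0.861, 3 of 23 fell and 1 rose; adjusted p = 0.62 with an estimated correlation) and ciliated cells (-0.402, none of 16 passed; adjusted p = 0.755 with an estimated correlation), and fry called neither. Less airway tissue in the sampled lung would lower both alike. The medians differed by 0.459 (95% bootstrap interval over the genes of the lists -0.0583 to 1.22, 10000 draws). This interval takes the genes as independent and holds no spread between mice, so it cannot decide the question. Less airway tissue may account for the change and stays open. The slide series stays open too: the club list had a median of -1.52 (adjusted p = 1.29e-05) with the series as a term, but 1 PBS array alone separates the series from the groups, and the condition on this was added to the test after its first run, which would have excluded the series. An effect of NNK on these cells stays open and was not tested.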

How the results depend on the processing

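Cyclic loess, the slide series and PBS 3 as the only PBS array were chosen after seeing the data; the other settings were planned. Of 191 values of comparisons under the alternatives, 147 stayed close, 2 lost their call, 39 moved and 3 reversed. Of 2457 list values 2219 kept direction and call, 130 lost and 100 gained a call and 8 reversed. Of 13517 values of named genes 12449 kept direction and call, 1040 lost the call and 28 reversed. The cause was not tested except where given. Signal over background limits dim genes: spots well above background made up 55.6% to 73.1% of an array, and a change is given as a bound only where no array of the dimmer group was above background; where only some were, the report gives their number. Scalings moved the median of all items by over 0.1 in log2: normexp gave 0.335 (LPS against PBS), 0.555 (NNK against PBS), 0.532 (LPS/NNK against PBS), -0.175 (LPS/NNK against NNK), 0.311 (LPS/NNK against LPS) and -0.385 (interaction). Before, these medians were -0.0608, 0.0368, -0.0384, -0.0602, 0.109 and 0.00983. Scaling to the median of the tested genes gave 0.0858 for LPS against PBS, 0.0668 for LPS/NNK against PBS and -0.125 for the interaction, and cyclic loess -0.0876 for NNK against PBS.

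Normexp raised the median residual SD from 0.379 to 0.48 and called 4124 items for LPS against PBS, 6470 for LPS/NNK against PBS, 353 for LPS/NNK against NNK, 0 in limma for LPS/NNK against LPS (1522 at an unadjusted p under 0.05) and 71 for the interaction. With no filter 32946 items were tested and 19478, 17557, 18656, 2515, 338 and 13186 called, in the order LPS, NNK and LPS/NNK against PBS, LPS/NNK against NNK, against LPS, and interaction. LPS/NNK against LPS had 1562 with every probe by itself (more probes tested), 38 from only the groups compared (fewer arrays) and 1 with the slide series. The slide as a fixed block gave 6638 for NNK against PBS, and the slide series 7763 for LPS against PBS and 4616 for the interaction. PBS 3 as the only PBS array (fewer arrays) gave 5691, 4295 and 6615 for LPS, NNK and LPS/NNK against PBS and 2630 for the interaction. Of 56 list calls by camera 0 held with an estimated correlation (13 of 162 tests at an unadjusted p under 0.05; fry called 47).

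Leaving out single arrays gave 78 to 4825 for LPS/NNK against LPS: 296 without LPS 1, 359 without LPS 5, 569 without LPS 6, 4825 without LPS/NNK 2, 78 without LPS/NNK 3 and 111 without LPS/NNK 6. It gave 1576 to 5813 for LPS/NNK against NNK: 1631 without NNK 2, 1576 without NNK 3, 2950 without NNK 5, 5813 without LPS/NNK 2, 1790 without LPS/NNK 3 and 2025 without LPS/NNK 6. The correlation of the LPS effect without and with NNK ranged from 0.226 to 0.402 (0.268 without NNK 5, 0.226 without LPS/NNK 2, 0.402 without LPS/NNK 6). The correlation of the NNK effect without and with LPS ranged from -0.105 to 0.0205 (-0.0139 without PBS 1, -0.105 without NNK 5, -0.0956 without LPS/NNK 2, and reversed to 0.00223 without NNK 2 and 0.0205 without LPS/NNK 6), was -0.113 over genes well above background on all 12 arrays and 0.00541 with PBS 3 as the only PBS array.

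The numbers in the titles were not taken as pairs, since 3 of 9 same-number pairs correlated over 0.1 and 4 of 12 arrays correlated best with their own number; the replicate block gave 1890 for LPS/NNK against LPS and reversed the chemokine list there (median 1.02). It ended 1 list call, that of clock and immediate-early genes in LPS/NNK against NNK (median -0.356, adjusted p = 0.104), and added 5.

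Other lists reversed against other genes. Under normexp, for NNK against PBS, these were alveolar type 2 (median 0.366) and matrix (0.364), which lost their call, and alveolar type 1 (-0.0463) and endothelial (-0.109), which were called down (adjusted p = 0.012 and 0.00315; 0.932 and 0.919 with an estimated correlation and without normexp). With the slide series, for LPS/NNK against LPS, they were monocyte (-0.405), proliferation (-0.19) and interferon response (-0.494). Genes that reversed under normexp were Cpa3 (0.12) for LPS against PBS. For NNK against PBS they were Steap4 (0.18), Btla (0.083), Cd38 (0.19), Ncr1 (0.077), Icos (0.57), Cpa3 (1.13), Il1rl1 (0.18), Sntn (0.40), Enkur (0.32) and Nusap1 (0.064). For LPS/NNK against PBS they were Ccl24 (0.18), Cpa3 (0.79), Sntn (0.032) and Hmga2 (0.51). They were Il1r2 (-0.0078) and Ahrr (-0.058) for LPS/NNK against NNK, and Trat1 (-0.52), Fasl (-0.14), Cd200r1 (-0.52), Siglech (-0.26) and Hmga2 (-0.17) for the interaction. Hba-a1 reversed under quantile normalization to -0.34 (LPS against PBS), -0.0048 (NNK against PBS) and -0.69 (LPS/NNK against PBS) and under cyclic loess to -0.34 (LPS against PBS) and -0.82 (LPS/NNK against PBS), where Wfdc2 was at -0.034.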
